A study of Homo sapiens with 18 samples.

How the data were processed

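The series holds 18 libraries in 9 groups of 2, per the labels, all from HEK293T cells. Of these, 10 libraries in 5 groups stand behind the 3 gene tables used here: wild-type (WT) cells after 6 h with the DMSO vehicle, with Torin 1 at 250 nM or with tunicamycin at 1 µM, and ATF4-null cells after 6 h with the vehicle or the same Torin 1 dose. Their libraries were made with a stranded SMARTer total RNA kit, per the labels. The other 8 libraries come from a 24 h Torin 1 experiment, with 4 ribosome footprint libraries and 4 matched RNA libraries, and were not analysed here. Nothing in the labels says that the 2 replicates of a group are separate cultures, so a p-value speaks at most for these samples. The settings of the authors' test are not stated, so how its p-values use the 2 replicates is unknown.

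Per the submitters' processing notes, the human genome build was hg19 and the programs were CASAVA, Bowtie2 2.2.9, TopHat2 2.1.1 and Cufflinks 2.2.1. The notes give no role, order or setting for any of them, and the gene annotation is not stated. Per the file headers, the tables have the layout of Cuffdiff, the testing program that belongs to Cufflinks. Expression is in FPKM (fragments scaled for transcript length and library size) in the authors' tables, with 1 value per group that pools both replicates, scaled by the authors within each table only. The deposited fold changes are log2 of the second group over the first, and they were recomputed from the deposited FPKM to within 4.92e-05. The score in the authors' tables is the test statistic of each gene. The deposited p-value is that of the authors' test of each gene, and the deposited q-value is its Benjamini-Hochberg adjustment over the genes tested in that table, which was recomputed to within 5.27e-07.

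The headers call the groups of each table only first and second, so the order of control and then treatment was taken from the deposited table names. For the WT tables this order was checked: the first group of both has the same profile, with a median ratio of 0.953 and a 1st to 99th percentile of 0.950 to 0.956 over 15281 genes. For the ATF4-null table the same order was assumed, and every ATF4-null direction rests on that. Genes called in both Torin 1 tables argue against a reversed order, under which they would respond oppositely in the 2 genotypes. Of those lower in WT cells, 54 were lower and 1 higher in ATF4-null cells, and of those higher in WT cells, 15 were higher and 0 lower. The tables give no value per library, so no SD, outlier test, regrouping of samples or fit without a replicate could be computed, and the depth of each library is unknown.

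Each table lists 28503 genes. A gene was counted as higher or lower when the authors' q was under 0.05 and the gene was marked as tested, which held for 11291 genes with Torin 1 in WT cells, 11483 with Torin 1 in ATF4-null cells and 11453 with tunicamycin. The smallest deposited p, 5e-05, was reached by 72, 286 and 490 genes in these tables. Called genes with an infinite fold were ASIP with Torin 1 in ATF4-null cells, and GNRH2, HIST1H2BB and MIR378D2 with tunicamycin. Each is listed at 0 in a group and gets no fold. Of the 12263 gene identifiers tested in any table, 10602 (86.5%) are current symbols. Identifiers were kept as the tables give them, since the name table used holds no older symbols.

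Differences between comparisons were tested per gene with a two-sided z test on the difference of log2 folds, with Benjamini-Hochberg adjustment and a threshold of 0.05. The standard error (SE) of a fold was its size divided by the normal deviate of the deposited p, which at the smallest p is an upper limit. Above a p of 0.9 the SE came from the deposited statistic. The test needed FPKM of at least 1 in a group, which removed no tested gene. It covered 10750 genes for WT against ATF4-null cells and 10857 genes for tunicamycin against Torin 1 in WT cells. In the second test the shared control cancels, so the summed variance is too large. With 1 value per group, no exact or permutation test could be run. These p-values rest on a normal approximation and on the error that the authors' test estimated, by settings not stated, with 2 libraries per group.

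Altogether 28 gene lists with 668 members were fixed, of which 24 had enough measured members for a median. Each list was given its count of called genes over all genes, its count adjusted over the list alone, its median log2 fold with a 95% bootstrap interval from 10000 draws, and the percentile of that median among 10000 random lists of the same size, drawn with replacement in 20 bins of expression. The percentiles describe these tables and allow for no correlation between genes. Named genes were ATF4, the 10 highest and 10 lowest called folds or differences per comparison with FPKM of at least 5 in the higher group, up to 4 members per list and comparison, and 15 genes of the overlap between the treatments. Small RNA genes were left out of the naming.

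The thresholds, lists, naming rule, tests and first set of alternatives were fixed before the data were examined. That set held a threshold of 0.01, FPKM minimums of 1 and 5 or none, adjustment over the 3 tables together, folds centred on their median, FPKM rescaled to a common sum, small RNA genes left out, pseudocounts of 1 and 0.1, means in place of medians and SEs from the statistic. Chosen after the data were seen were the SE from the statistic only where p is the smallest, the rule above a p of 0.9, the 20 bins, the clipping of folds at -3 and 3 in the simulation of a shared control, the drawing of matched sets from the 10 nearest genes, the comparison of control levels between genotypes, the response to tunicamycin of the genes that differed by genotype, the control level of all 9 genes lower with both treatments, the rescaling of list medians to a common sum, and a verdict on each explanation that takes the bootstrap interval into account. Control levels of the 2 genotypes come from separately scaled tables and were centred on their median log2 ratio of 0.02 over 10758 genes, without a test.

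The difference test was tested on simulated data with 50 changed genes per size. With the SE from p, it recovered 8% of genotype differences of 1 on the log2 scale and 48% of those of 2, with 1 false call in 39. With the SE from the statistic it recovered 36% and 88%, with 4 false calls in 104. The noise and the statistic were simulated from the same SE, so the SE from the statistic was exact there by construction. The false calls therefore do not show how well either SE holds in the authors' tables. In simulated tables, a list shifted by 0.4 reached percentile 99.6, and 9 of 200 unshifted lists fell outside the 2.5 to 97.5 percentiles. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.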

Results

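The gene tables describe RNA from HEK293T cells, a human embryonic kidney line, that were wild type (WT) or lacked ATF4. ATF4 is a transcription factor of the integrated stress response that activates genes of amino acid synthesis and transport. For 6 h the cells received vehicle, Torin 1 at 250 nM, which inhibits the mTOR kinase, or tunicamycin at 1 µM, which blocks N-linked glycosylation and stresses the endoplasmic reticulum (ER). The 5 groups of 2 libraries were WT vehicle, WT Torin 1, WT tunicamycin, ATF4-null vehicle and ATF4-null Torin 1. The title of the series concerns how the mTOR complex mTORC1 controls ATF4, so the comparisons ask which transcripts change when mTOR is inhibited, which of these changes differ in ATF4-null cells, and how they compare with ER stress. FPKM, folds and q-values of single genes are the authors', while medians, overlaps and tests of differences were computed here. Each table holds 1 value per group, so no replicate error can be given for FPKM values, and the depth is unknown.

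ATF4 (chromosome 22, 39916569 to 39918691 in hg19) was lower after Torin 1 in WT cells, at 512 FPKM with vehicle and 189 with Torin 1 (log2 fold -1.44, q = 0.00784, the authors' deposited table). In ATF4-null cells its mRNA was still listed in the authors' deposited table, at 250 FPKM with vehicle and 277 with Torin 1 (log2 fold 0.15, q = 0.655). Tunicamycin gave 614 FPKM in WT cells and a log2 fold of 0.33 that did not pass the test (q = 0.138, the authors' deposited table). The kind of null allele is not stated in the labels, and an mRNA level does not show whether protein is made. The difference between genotypes in the Torin 1 response of ATF4 was -1.58, with an adjusted p of 0.0555 with the SE from p and 8.99e-11 with the SE from the statistic at the smallest p, which was chosen after the data were seen.

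Torin 1 in WT cells lowered transcripts of stress regulators and of amino acid supply. DDIT4, which restrains mTORC1, fell from 67.9 to 5.49 FPKM (log2 fold -3.63, q = 0.00784), and SLC7A11, the cystine and glutamate exchanger, fell from 24.1 to 1.96 FPKM (log2 fold -3.62, q = 0.00784), both in the authors' deposited table. The transcription factor ATF3 (log2 fold -2.39), the leucine-binding stress protein SESN2 (-2.37), the secreted glycoprotein STC2 (-2.31) and the transcription factor CEBPB (-1.93) also fell in the authors' deposited table. Of 12 measured stress response regulators, 8 fell and none rose, and 8 fell adjusted over the list alone, with a median log2 fold of -1.68 (95% bootstrap interval -2.38 to -1.26) at percentile 0 of matched random lists. Of 20 amino acid synthesis genes 8 fell, and 10 fell adjusted over the list alone, with a median of -0.51 (-0.64 to -0.30, percentile 0). Among them were PSAT1 of serine synthesis (log2 fold -1.63) and CTH, which makes cysteine (-1.60), in the authors' deposited table. Of 19 amino acid transporters 7 fell, and 10 fell adjusted over the list alone, with a median of -0.65 (-1.21 to 0.09, percentile 0). SLC7A5, which imports leucine, had a log2 fold of -2.34 and SLC7A1, which imports arginine and lysine, -1.17, both called in the authors' deposited table. Of 20 cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, 8 fell, and 9 fell adjusted over the list alone, with a median of -0.28 (-0.71 to -0.19, percentile 0.01). GARS (log2 fold -1.27) and YARS (-1.15) fell most among them in the authors' deposited table. None of 17 mitochondrial synthetases was called, and 1 was lower adjusted over the list alone, with a median of 0.09 (-0.06 to 0.16).

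Single genes of lipid synthesis also fell after Torin 1 in WT cells. Of 24 cholesterol genes 2 fell, HMGCS1 of the mevalonate pathway (log2 fold -0.97) and INSIG1, a regulator of sterol synthesis (-0.76), in the authors' deposited table. Adjusted over the list alone 6 fell, and the list median was -0.25 (-0.47 to -0.06, percentile 0.01). Of 11 fatty acid synthesis genes 2 fell, and 2 fell adjusted over the list alone, with a median of -0.30 (-0.51 to 0.02, percentile 0.1). They were ELOVL5, a fatty acid elongase (log2 fold -1.93), and FASN, the fatty acid synthase (-0.92), in the authors' deposited table. ELOVL5 fell as much with tunicamycin (log2 fold -1.99), and its centred log2 ratio of ATF4-null over WT vehicle was -1.96. A high WT vehicle value is therefore not excluded for ELOVL5. Of 40 ribosome biogenesis genes 1 fell, the nucleolar protein gene LYAR (log2 fold -0.73, the authors' deposited table), and 4 fell adjusted over the list alone, with a median of -0.27 (-0.34 to -0.25, percentile 0). ER chaperone genes included 3 that fell out of 32, among them the chaperone gene HSPA5 (log2 fold -0.73) and XBP1, a transcription factor of the unfolded protein response (-1.33), in the authors' deposited table. Adjusted over the list alone 6 fell, with a list median of -0.12 (-0.28 to -0.03, percentile 3.93) that was -0.01 with FPKM rescaled to a common sum.

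Among the transcripts that rose, KITLG, the ligand of the KIT receptor, had the highest log2 fold among the named genes (2.74, 6.85 to 45.9 FPKM, q = 0.0264, the authors' deposited table). TCP11L2 (1.34), ZNF396 (1.30), SEPSECS, an enzyme of selenocysteine tRNA synthesis (1.13), and YPEL2 (1.10) also rose in the authors' deposited table. Of 25 FOXO target genes, which respond to transcription factors that AKT restrains, 2 rose, KLHL24 (log2 fold 0.95) and YPEL5 (1.04) in the authors' deposited table, and 5 rose adjusted over the list alone, with a median of 0.38 (0.06 to 0.54, percentile 100). None of 77 ribosomal protein genes was called, over all genes or adjusted over the list alone, and their median was 0.12 (0.09 to 0.15, percentile 100). None of 34 lysosome and autophagy genes was called by either count, with a median of 0.13 (0.05 to 0.20, percentile 98.5).

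Over all genes, 21 were higher and 105 lower of 11291 tested after Torin 1 in WT cells at q under 0.05 in the authors' deposited table, and 1102 had an unadjusted p under 0.05. The total FPKM was lower with Torin 1 by 0.11 on the log2 scale (-0.11), and with both groups rescaled to the same sum 70 genes were higher and 54 lower. Under that scaling the list medians of stress regulators, amino acid synthesis, transporters, cytosolic synthetases, cholesterol and fatty acid synthesis and ribosome biogenesis stayed below 0, at -1.57, -0.40, -0.54, -0.17, -0.14, -0.19 and -0.17. COL1A2, a collagen chain that marks fibroblasts, was the lowest named gene (51.8 to 1.20 FPKM, log2 fold -5.43, q = 0.0186, the authors' deposited table), and its level was 0.899 FPKM in the ATF4-null vehicle group. COL1A1 of the same collagen stood at 3.72 FPKM with vehicle and 4.24 with Torin 1 (q = 0.868, the authors' deposited table).

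Torin 1 in ATF4-null cells lowered the transcripts of 19 of 40 ribosome biogenesis genes. MKI67, a marker of proliferating cells, fell from 51.7 to 5.61 FPKM (log2 fold -3.20), the linker histone gene HIST1H1E from 504 to 22.2 FPKM (-4.50) and TOP1, a DNA topoisomerase, from 174 to 31.0 FPKM (-2.48), each with q = 0.00201 in the authors' deposited table. The chromatin protein gene HMGN5 (log2 fold -3.36), GPATCH4 (-2.93) and RRBP1, an ER ribosome-binding protein (-2.60), also fell in the authors' deposited table. Of 25 replication-dependent histone genes, the list of HIST1H1E, 5 rose and 2 fell, and adjusted over the list alone 6 rose and 2 fell, with a median of 0.10 (0.01 to 0.31, percentile 94.2) and a mean of -0.07. Of 20 G2/M genes, the list of MKI67, 2 fell, and 3 fell adjusted over the list alone, with a median of -0.06 (-0.24 to 0.05, percentile 42.8). None of the ribosome biogenesis genes rose over all genes, and adjusted over the list alone 20 fell and 1 rose, with a median of -0.51 (-0.70 to -0.36, percentile 0). LYAR (log2 fold -2.33), NOLC1 (-1.46) and NCL (-1.40), all of the nucleolus, were among those that fell in the authors' deposited table. Highest among the named genes were RYR2, a calcium release channel (log2 fold 3.18, q = 0.00721), and RECK, an inhibitor of metalloproteases (2.32, q = 0.00937), in the authors' deposited table. Of 24 FOXO target genes 9 rose and none fell, and 12 rose adjusted over the list alone, with a median of 0.55 (0.40 to 0.69, percentile 100). They included KLHL24 (log2 fold 1.57), the ubiquitin ligase gene FBXO32 (1.25), the insulin receptor gene INSR (0.53) and FOXO3 itself (0.52) in the authors' deposited table.

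Fewer of the amino acid supply genes were called in ATF4-null cells. None of 20 amino acid synthesis genes was called by either count, with a median of -0.09 (-0.17 to 0.01, percentile 26.4). Of 20 cytosolic synthetases 2 fell, YARS (log2 fold -0.56) and MARS (-0.51) in the authors' deposited table, and 2 fell adjusted over the list alone. Their median was -0.14 (-0.18 to 0.09, percentile 16.8). Of 16 transporters 3 fell and 1 rose, and adjusted over the list alone 3 fell and 2 rose, with a median of -0.17 (-0.42 to 0.10, percentile 6.27). SLC7A5 fell (log2 fold -1.41), as did SLC1A5, a glutamine transporter (-0.75), and SLC43A1 rose (0.89) in the authors' deposited table. Of 10 stress regulators 4 fell by all genes and 4 adjusted over the list alone, with a median of -0.44 (-1.0 to -0.10, percentile 0.18). DDIT4 had a log2 fold of -1.14 and CEBPB of -1.16 in the authors' deposited table. Of 24 cholesterol genes 7 fell, and 8 fell adjusted over the list alone, with a median of -0.24 (-0.54 to -0.07, percentile 0.55). HMGCS1 (log2 fold -1.15) and INSIG1 (-1.07) fell in the authors' deposited table. FASN (-0.97) was the fatty acid synthesis gene that fell out of 11 in the authors' deposited table, and 1 fell adjusted over the list alone.

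Over all genes, 258 were higher and 542 lower of 11483 tested in ATF4-null cells at q under 0.05 in the authors' deposited table, and 2224 had an unadjusted p under 0.05. Rescaled to the same sum, 388 were higher and 414 lower. Of the 105 genes lower with Torin 1 in WT cells, 100 were tested in ATF4-null cells, where 54 were lower, 1 was higher and 90 had the same sign. Independent lists would share 4.93 lower genes. The median log2 fold of the WT-lower genes was -0.86 in WT and -0.61 in ATF4-null cells. Of the 21 genes higher in WT cells, 20 were tested in ATF4-null cells, all with the same sign and 15 called higher, against 0.468 for independent lists.

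The test of the difference between genotypes asked which Torin 1 responses differed between WT and ATF4-null cells. TSC22D3, the glucocorticoid-induced leucine zipper gene, had a lower fold in WT than in ATF4-null cells, by -1.48 (SE 0.28, adjusted p = 0.000881, computed from the authors' p-values). Likewise computed from the p-values of the authors, the difference was below 0 for SLC38A2, a neutral amino acid transporter (-1.13, SE 0.23, adjusted p = 0.00541), and for ALDH1L2, a mitochondrial folate enzyme (-1.08, SE 0.25, adjusted p = 0.0308). HIST1H1D, a linker histone gene, had a higher fold in WT cells, by 2.21 (SE 0.48, adjusted p = 0.0114), and CCDC34 by 1.38 (SE 0.32, adjusted p = 0.0308), again from the authors' p-values. These were the 3 lower and 2 higher genes out of 10750 at an adjusted p under 0.05, and 522 had an unadjusted p under 0.05.

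The lists of amino acid synthesis, stress regulator and cytosolic synthetase genes had lower median differences than matched random lists, while few of their single genes passed the test of the difference. The median difference, WT minus ATF4-null, was -0.47 for amino acid synthesis (-0.75 to -0.23, percentile 0), -1.12 for stress regulators (-2.0 to -0.62, percentile 0), and -0.30 for cytosolic synthetases (-0.49 to -0.09, percentile 0). For the transporters it was -0.10 (-0.84 to 0.12, percentile 9.46). Over all genes the differences of 1 synthesis gene, ALDH1L2, and 1 transporter, SLC38A2, passed, and no synthetase or stress regulator did. With the SE from p, a gene at the smallest p in WT cells and with little change in ATF4-null cells could not pass here. ASNS, the asparagine synthetase, is an example, with log2 folds of -1.05 and 0.02 and an adjusted p of 0.159 in the test of the difference. The counts over all genes therefore do not show that such genes respond alike in both genotypes. Adjusted over the list alone, 5 of 20 synthesis genes, 5 of 16 transporters, 2 of 20 synthetases and 4 of 10 stress regulators had a lower fold in WT cells. Ribosome biogenesis genes had the opposite median difference, 0.30 (0.15 to 0.43, percentile 100), with none of 40 called over all genes and 1 lower adjusted over the list alone. Genes at the smallest p in ATF4-null cells and with little change in WT cells could not pass either. This count therefore does not show a like response in both genotypes. With the SE from the statistic at the smallest p, 4 of the 40 had a higher fold in WT cells and 0 a lower one. FOXO target genes had a median difference of -0.30 (-0.56 to -0.18, percentile 0.01), with none of 24 called by either count.

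The SE from p is an upper limit for genes at the smallest p. With the SE of those genes taken from the statistic, a choice made after the data were seen, 17 genes were lower and 60 higher in WT cells, and with the SE from the statistic for every gene, an alternative set in advance, 19 and 66. Among the 17 were DDIT4 (difference -2.49), ATF3 (-2.13), SESN2 (-2.0), CTH (-1.64), STC2 (-1.45), PSAT1 (-1.26) and ASNS, the asparagine synthetase (-1.08), and among the 60 were HIST1H1E (4.45), HMGN5 (3.19), MKI67 (2.71), LYAR (1.60) and NCL (1.02). The naming of several of these followed their values. Of the 105 genes lower in WT cells, 3 had a lower fold in WT cells with the SE from p and 16 with the SE from the statistic at the smallest p. In simulated data the SE from p found 48% of differences of 2 on the log2 scale.

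**Figure D1:**
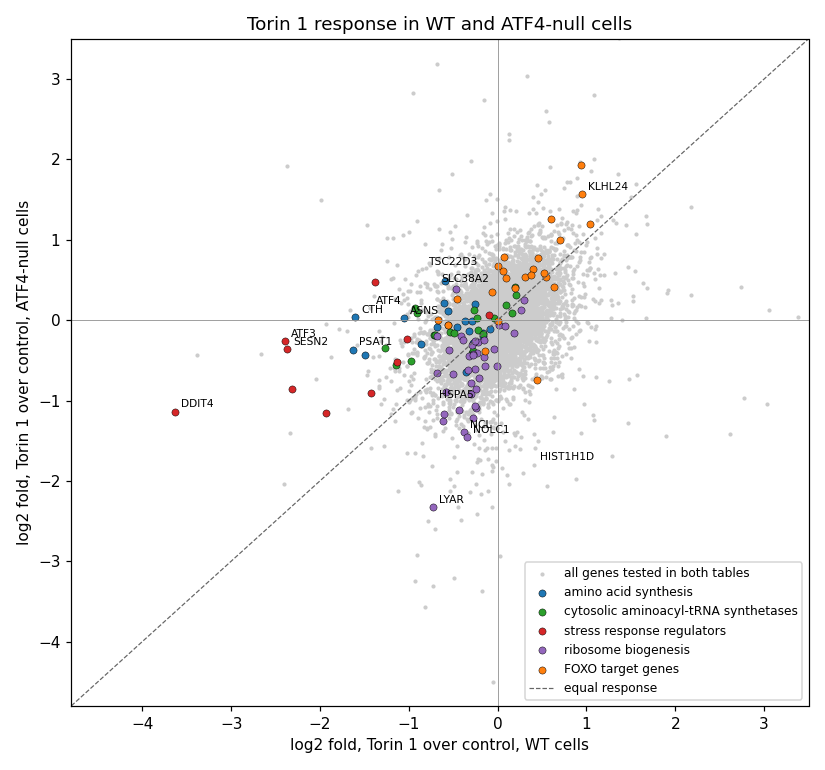
Log2 fold change with Torin 1 in WT cells (x axis) against ATF4-null cells (y axis) for 10750 genes tested in both tables, 6 of which lie outside the axes, with members of 5 lists coloured and the dashed line marking equal folds. DDIT4, ATF3, SESN2, CTH and PSAT1 lie far to the left with ATF4-null folds nearer 0, and the ribosome biogenesis genes LYAR, NOLC1 and NCL lie below the line.

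The vehicle groups of the 2 genotypes also differed in these lists, across tables scaled separately and without a test. The median centred log2 ratio of ATF4-null over WT vehicle was -1.61 for stress regulators (-1.78 to -0.78), -0.71 for amino acid synthesis (-1.22 to -0.22), -0.43 for cytosolic synthetases (-0.67 to -0.16) and -0.33 for transporters (-0.96 to 0.04), each at percentile 0. For ribosome biogenesis it was 0.05 (-0.02 to 0.16, percentile 75.9). In each of the other lists the ratio was larger in size than the median difference between genotypes. A high WT or low ATF4-null vehicle value is therefore not excluded for those differences. A high WT vehicle value would also lower the tunicamycin folds. Their medians were 0.45 for stress regulators and 0.23 for cytosolic synthetases, but -0.12 for amino acid synthesis and -0.28 for transporters.

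Tunicamycin in WT cells raised 21 of 31 genes for ER chaperones and ER-associated degradation. HSPA5, the main ER chaperone, rose from 98.5 to 898 FPKM (log2 fold 3.19, q = 0.00117, the authors' deposited table). MANF, a secreted ER stress protein (log2 fold 2.77), HERPUD1, of ER-associated degradation (2.56), SDF2L1 (2.30) and DNAJB9, a co-chaperone (2.17), also rose in the authors' deposited table. DDIT3, the stress transcription factor CHOP, had a log2 fold of 2.51 (q = 0.00522, the authors' deposited table). None of the ER chaperone and degradation genes fell over all genes, and adjusted over the list alone 22 rose and 1 fell, with a median of 1.08 (0.69 to 1.55, percentile 100). Of 15 stress regulators 5 rose and none fell, and 8 rose adjusted over the list alone, with a median of 0.45 (0.40 to 0.85, percentile 99.8). PPP1R15A, which directs dephosphorylation of eIF2 alpha (log2 fold 1.08), VEGFA, a growth factor (0.74), and JDP2 (0.79) were among them in the authors' deposited table. Of 26 genes of N-glycan and hexosamine synthesis 5 rose, and 5 rose adjusted over the list alone, with a median of -0.08 (-0.27 to 0.13, percentile 16.3). MPDU1 (log2 fold 1.76) and ALG2, a mannosyltransferase (0.90), were among them in the authors' deposited table.

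Part of the ribosome biogenesis and ribosomal protein genes rose with tunicamycin as well. Of 40 ribosome biogenesis genes 19 rose and none fell, and 20 rose adjusted over the list alone, with a median of 0.45 (0.21 to 0.66, percentile 99.9). LYAR (log2 fold 1.48) and RRS1 (1.20) rose in the authors' deposited table. Of 77 ribosomal protein genes 40 rose and 3 fell, and adjusted over the list alone 46 rose and 7 fell, with a median of 0.47 (0.30 to 0.65, percentile 98.5). Matched random lists had a median of 0.33 (0.17 to 0.46), so genes of like expression also lay above 0 in this table. RPL36 (log2 fold 2.12) was among those that rose, and RPL10 (-0.63) and RPS7 (-0.53) were among those that fell in the authors' deposited table. Of 20 cytosolic synthetases 4 rose, and adjusted over the list alone 6 rose and 1 fell, with a median of 0.23 (0.12 to 0.42, percentile 45.1). NARS (log2 fold 0.61), SARS (0.58), AARS (0.48) and CARS (0.47) rose in the authors' deposited table.

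In the transporter, amino acid synthesis and lysosome lists few genes were called with tunicamycin, and the list medians were negative. Of 19 transporters 3 fell and 1 rose, with the same numbers adjusted over the list alone, and a median of -0.28 (-0.39 to -0.14, percentile 0.76). SLC3A2, the heavy chain shared by several transporters, rose (log2 fold 0.72), and SLC6A15 (-0.80) and SLC38A2 (-0.64) fell in the authors' deposited table. Of 20 amino acid synthesis genes 2 fell by all genes and 2 adjusted over the list alone, GLUL, the glutamine synthetase (log2 fold -0.78), and GOT2, an aspartate aminotransferase (-0.49), in the authors' deposited table, with a list median of -0.12 (-0.21 to 0.04, percentile 2.65). Of 33 lysosome and autophagy genes 4 fell, and adjusted over the list alone 4 fell and 1 rose, with a median of -0.29 (-0.41 to -0.16, percentile 0.225). LAMP2 (log2 fold -0.67) and LAMP1 (-0.57), both lysosome membrane proteins, were among them in the authors' deposited table. The lowest named genes were COL1A2 (log2 fold -6.30), TRPM2, a cation channel (-2.46), and C1orf112 (-2.26), and the highest was TCRA (5.55, from 17.8 to 832 FPKM), listed for the T cell receptor alpha locus at chromosome 14, 22192008 to 23021097, all in the authors' deposited tables.

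Over all genes, 961 were higher and 508 lower of 11453 tested with tunicamycin at q under 0.05 in the authors' deposited table, and 2881 had an unadjusted p under 0.05. With both groups rescaled to the same sum, which takes 0.09 off each log2 fold, 749 were higher and 871 lower. Under that scaling the tunicamycin medians of ER chaperones, stress regulators, ribosome biogenesis, ribosomal proteins and cytosolic synthetases stayed above 0, and that of translation factors went from 0.05 to -0.04.

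**Figure D2:**
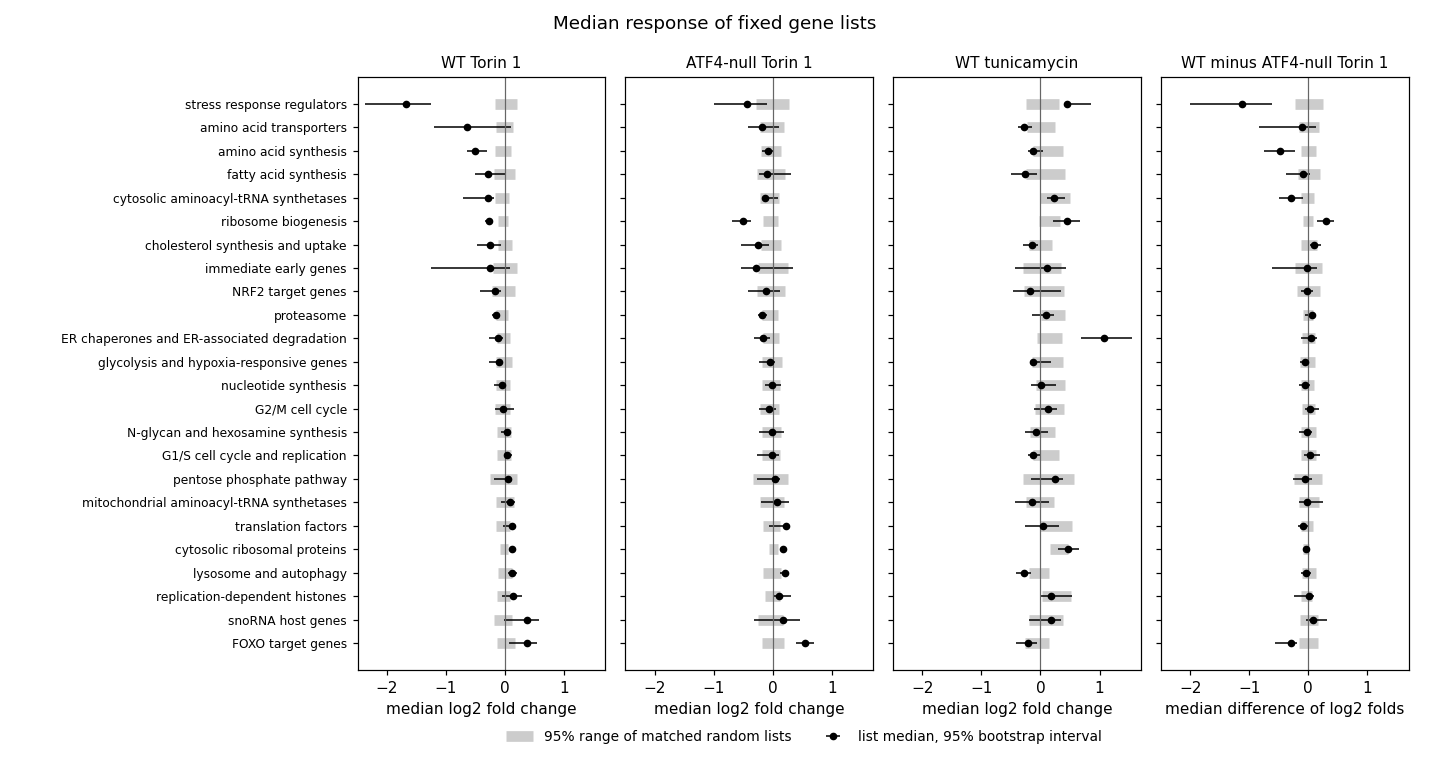
Median log2 fold change of 24 gene lists (y axis) in the 3 tables and median difference between genotypes (right panel), on a common log2 x axis, with dots for list medians, lines for 95% bootstrap intervals and grey bars for the 95% range of matched random lists. Stress regulators lie at -1.68 with Torin 1 in WT cells (12 measured members), -0.44 in ATF4-null cells (10) and 0.45 with tunicamycin (15), and ER chaperones at 1.08 with tunicamycin. The members measured differ between the 3 tables, so these medians do not cover the same genes.

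The responses of WT cells to tunicamycin and to Torin 1 were compared to separate ER stress from mTOR inhibition. Computed from the authors' p-values, the tunicamycin fold was higher for DDIT4 by 4.08 (SE 0.91, adjusted p = 0.00116), HSPA5 by 3.92 (SE 0.81, adjusted p = 0.000525), DDIT3 by 3.89 (SE 0.99, adjusted p = 0.00454) and SLC7A11 by 3.48 (SE 0.91, adjusted p = 0.00568). HSPA5 and DDIT3 were called higher with tunicamycin. DDIT4, with a log2 fold of 0.45 with tunicamycin and -3.63 with Torin 1, was not, and neither was SLC7A11. The differences of DDIT4 and SLC7A11 thus came mainly from their fall with Torin 1. The tunicamycin fold was lower for KITLG by -3.04 (SE 0.87, adjusted p = 0.0126) and for TRPM2 by -2.35 (SE 0.64, adjusted p = 0.0081), from the authors' p-values. FOXO1, a FOXO factor gene, differed by -1.20 (adjusted p = 0.00325) and KLHL24 by -1.55 (adjusted p = 0.00062), on the same basis in the authors' p-values. Of 10857 genes, 582 had a higher and 226 a lower tunicamycin fold at an adjusted p under 0.05, and 2116 had an unadjusted p under 0.05.

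In WT cells 22 genes were lower with Torin 1 and higher with tunicamycin, where independent lists would share 8.89. The 15 named by the largest difference included the ER genes HSPA5, HERPUD1 and XBP1, the stress genes TRIB3 and VEGFA, the transporter chain SLC3A2, the synthetases CARS and AARS, and EIF4EBP1, a translation repressor that mTORC1 phosphorylates. The others were LYAR, MAP1B, ANKRD11, ABCF1, DBN1 and SRRT. Lower with both were 9 genes against 4.85 for independent lists, among them INSIG1, ELOVL5 and SLC38A2. None was higher with both (1.44 for independent lists) or higher with Torin 1 and lower with tunicamycin (0.785). Both tables share the vehicle group, and unchanged groups simulated against a shared control gave the same sign for 66.7% of genes, compared with 51.0% here. The simulation held no changed genes, so calls in both were not to be found in it (0, with 31 here). It cannot show what a shared control does to the overlap.

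In ATF4-null cells the 22 genes had a median Torin 1 fold of -0.71 (-0.94 to -0.28), against -0.73 in WT cells. HERPUD1 (log2 fold -0.10), EIF4EBP1 (-0.15), CARS (0.15) and AARS (0.09) did not pass the test there, and HSPA5 (-1.03), XBP1 (-0.82), LYAR (-2.33) and MAP1B, a microtubule protein (-2.01), fell, all in the authors' deposited table. HSPA5, XBP1, LYAR and MAP1B are thus among the 170 genes lower with Torin 1 in ATF4-null cells and higher with tunicamycin. A shift of transcript composition, taken up below as a candidate for those genes, is not excluded here either. Sets drawn from 78 other genes lower in WT cells, matched on WT fold and expression, had a median of -0.66 (-0.89 to -0.36), which placed the 22 genes at percentile 28.9. No difference from the matched sets was detectable. The 78 genes include stress and amino acid genes such as DDIT4, STC2 and SLC7A5, whose folds may depend on ATF4 as well. The comparison therefore cannot show whether the folds of the 22 genes depend on ATF4.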

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

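The tests of explanations below were set before their results were seen. The SE from the statistic at the smallest p, the tunicamycin response and vehicle levels of the genes that differed by genotype and the use of bootstrap intervals in the verdicts were chosen only after the results were seen.

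The Torin 1 response differed between WT and ATF4-null cells, by a test of the difference itself, with a lower WT fold for 3 genes and a higher WT fold for 2. With the SE from p, genes at the smallest p in 1 genotype and with little change in the other could not pass. These counts leave them out. TSC22D3 (-1.48), the amino acid transporter SLC38A2 (-1.13) and the folate enzyme ALDH1L2 (-1.08) were lower, with WT folds of -0.85, -0.71 and -0.59 and ATF4-null folds of 0.63, 0.42 and 0.49 in the authors' deposited tables. Of these ATF4-null folds, that of TSC22D3 passed the authors' test (q = 0.0116). The ATF4-null vehicle levels of these 3 genes over WT vehicle, centred and without a test, were -1.75, -1.09 and -1.49, about as large as the differences, so a high value in the WT vehicle group, left open below for the genes lower with both treatments, SLC38A2 among them, is not excluded for these differences. A low level in the ATF4-null vehicle group gives the same ratio. A high WT vehicle value would also lower the tunicamycin fold, which was -0.64 for SLC38A2 but 0.43 for ALDH1L2 (q = 0.0571, the authors' deposited table). The linker histone gene HIST1H1D (2.21) and CCDC34 (1.38) were higher, with WT folds of 0.41 and 0.36 and ATF4-null folds of -1.80 and -1.02 in the authors' deposited tables.

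In ATF4-null cells 542 genes were lower with Torin 1, against 105 in WT cells, with 531 against 176 when adjusted over the 3 tables together and 414 against 54 with FPKM rescaled to a common sum. A shift of transcript composition that the tunicamycin libraries also show, in the other direction, is a candidate explanation: 170 of these genes were higher with tunicamycin in WT cells, where independent lists give 46.4 and no library is shared. This count cannot decide the question, because opposite responses of the same genes to the treatments would give the same overlap. No base or codon content was checked. An ATF4-null vehicle group that stands apart is argued against as the whole cause. These genes stood there at a median of 0.18 over WT vehicle (95% bootstrap interval 0.15 to 0.20), below 0.5 of the size of their fold of -0.78. With Torin 1 in ATF4-null cells they stood at -0.61 over WT vehicle. They were chosen for a low value in that group, so this level adds no support. A contribution stays open because the interval of the vehicle level includes 0.25 of the size of the fold of -0.78. That was the bound set for excluding it. The same response as in WT cells, passing the test more often, stays open. The WT median of these genes was -0.30 (-0.33 to -0.27), between 0.25 and 0.5 of the ATF4-null median, with 492 of 533 of the same sign. These genes were chosen by their ATF4-null fold, which enlarges that fold beside the WT fold, so the medians cannot decide this. Loss of ATF4 itself stays among the open explanations, as untested, because the design gives no second set of ATF4-null libraries.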

How the results depend on the processing

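Of 74 alternative values of the counts and the set median, 54 stayed within 1.5 times the main value or within its spread and 20 moved. A threshold of 0.01 gave fewer genes by construction: 9 higher and 63 lower with Torin 1 in WT cells, 113 and 316 in ATF4-null cells, 595 and 187 with tunicamycin, 0 genes with a higher WT fold, 281 and 65 with a higher and a lower tunicamycin fold, and 7 genes lower with Torin 1 and higher with tunicamycin. Adjustment over the 3 tables together gave 79 higher and 176 lower with Torin 1 in WT cells, as the other tables hold more small p-values. FPKM rescaled to a common sum shifted all folds of a table and gave 70 higher and 54 lower with Torin 1 in WT cells (75 genes shared with the main calls), 388 higher in ATF4-null cells and 871 lower with tunicamycin. The SE from the statistic gave 19 genes with a lower and 66 with a higher WT fold, and the SE from the statistic at the smallest p, chosen after the data were seen, 17 and 60, because the SE from p is an upper limit there. Of 672 alternative list values 643 stayed within their spread and 28 moved, and 1 was the change of sign of a list outside the range of matched random lists: translation factors with Torin 1 in WT cells had a median of 0.12 and a mean of -0.0169, and the cause was not tested. Inside that range more signs changed. Of 96 list medians 8 differed in sign from the mean, 2 of them beyond their spread, G1/S genes with Torin 1 in WT cells (0.04 and -0.08) and replication-dependent histones in ATF4-null cells (0.10 and -0.07). With FPKM rescaled to a common sum, added for lists after the data were seen, 14 changed sign, 2 of them beyond their spread, nucleotide synthesis with Torin 1 in WT cells (-0.05 to 0.05) and the genotype difference of ribosomal proteins (-0.05 to 0.00149). Of 299 alternatives for single genes 292 kept their direction and side of the threshold, 4 passed it (DDIT4 and NCL, genotype difference, SE from the statistic) and 3 no longer did (HIST1H1D, CCDC34 and ALDH1L2 at 0.01). The FPKM minimum of 1 removed no tested gene and says nothing about stability. No paired analysis was possible because the tables give 1 pooled value per group, and for the same reason leaving out each replicate was not run. Depth per library is unknown, and no tested gene had FPKM under 3.33 in its higher group, so nothing is shown for weakly expressed genes.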

Other observations

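The response to tunicamycin of the genes that differed by genotype, the correlations across genes, and the control level of all 9 genes lower with both treatments were chosen only after the results were seen, while the tests of explanations were set before.

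Cell cycle, early response and translation genes had small or mixed responses. Cyclin genes CCND2 and CCND1, which drive entry into the cell cycle, fell with Torin 1 in WT cells (log2 folds -1.68 and -0.71) and in ATF4-null cells (-1.10 and -1.41), in the authors' deposited tables. They were the 2 of 24 genes of the G1/S list that fell in WT cells, with 2 lower and 1 higher adjusted over the list alone, while in ATF4-null cells 5 fell and 2 rose, and with tunicamycin 1 fell and 1 rose, the same numbers as adjusted over the list alone. JUN and ATF3 were the 2 of 13 immediate early genes that fell in WT cells, with 5 lower and 1 higher adjusted over the list alone. JUN fell in both genotypes (log2 folds -1.42 and -1.59), in the authors' deposited tables. Of 12 immediate early genes in ATF4-null cells 1 fell and 1 rose, with 2 each way adjusted over the list alone, and of 13 with tunicamycin none was called by either count. None of 20 G2/M genes was called with Torin 1 in WT cells by either count. In ATF4-null cells 2 fell, with 3 adjusted over the list alone, and with tunicamycin 3 rose, with 3 adjusted over the list alone. Of 20 translation factors 3 fell with Torin 1 in WT cells, EIF4EBP1, EIF2S2 and EIF4G1, with 3 lower and 1 higher adjusted over the list alone. In ATF4-null cells 2 fell and 1 rose, and with tunicamycin 4 rose and 4 fell, the same numbers as adjusted over the list alone. The median with tunicamycin, 0.05, was -0.04 after rescaling to a common sum.

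Among metabolic and stress lists, HK2, a hexokinase, fell in both genotypes with Torin 1 (log2 folds -1.16 and -1.26), in the authors' deposited tables. It was the gene that fell of 22 glycolysis and hypoxia genes in WT cells, with 2 lower adjusted over the list alone. In ATF4-null cells 3 of 21 fell, with 4 adjusted over the list alone, and with tunicamycin 4 of 23 fell and 1 rose, the same adjusted over the list alone. The nucleotide synthesis gene IMPDH1 (log2 folds -0.70 and -0.73) and the heme oxygenase gene HMOX1 of the NRF2 list (-1.20 and -1.17) also fell with Torin 1 in both genotypes, in the authors' deposited tables. Nucleotide synthesis had 1 of 23 genes lower in WT cells, 2 lower in ATF4-null cells, and 2 higher and 1 lower with tunicamycin, with 1, 2, and 2 and 2 adjusted over the list alone. The NRF2 list had 1 of 11 lower, 1 of 10 lower, and 1 of 11 higher and 1 lower, with 2, 1, and 1 and 1 adjusted over the list alone. None of 31 proteasome genes was called with Torin 1 in WT cells by either count. In ATF4-null cells 2 fell, with 2 adjusted over the list alone, and with tunicamycin 3 rose and 2 fell, with 3 and 3 adjusted over the list alone. None of 7 pentose phosphate genes was called in any table by either count. Of 11 fatty acid synthesis genes 1 fell with tunicamycin, ELOVL5, with 2 adjusted over the list alone. Of 24 cholesterol genes 2 rose and 2 fell with tunicamycin, with 2 and 3 adjusted over the list alone, and of 22 FOXO target genes 1 fell, FOXO1, with 1 adjusted over the list alone. In ATF4-null cells 6 of 32 ER chaperone genes fell with Torin 1, with 8 adjusted over the list alone, 3 of 77 ribosomal protein genes rose, with 3 adjusted over the list alone, 1 of 17 mitochondrial synthetases fell, with 1 adjusted over the list alone, and 1 of 34 lysosome genes rose, with 0 adjusted over the list alone. None of 17 mitochondrial synthetases was called with tunicamycin, and none of 25 N-glycan genes with Torin 1 in either genotype, by either count.

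Replication-dependent histone genes went both ways. None of 26 was called with Torin 1 in WT cells by either count, 5 of 25 rose and 2 fell in ATF4-null cells, with 6 and 2 adjusted over the list alone, and 8 of 27 rose and 1 fell with tunicamycin, with 8 and 1 adjusted over the list alone. The median in ATF4-null cells was 0.10 and the mean -0.07, and the 2 that fell were the linker histone genes HIST1H1E and HIST1H1D (log2 folds -4.50 and -1.80, the authors' deposited table). Of 12 snoRNA host genes none was called with Torin 1 in WT cells, with 1 higher adjusted over the list alone and a median of 0.38 (-0.01 to 0.58, percentile 100). SNHG1 rose in ATF4-null cells and SNHG16 fell with tunicamycin, each with 1 adjusted over the list alone. MALAT1 and NEAT1, nuclear RNAs, were not called with Torin 1 over all genes and both were lower in each genotype adjusted over the list alone, and with tunicamycin NEAT1 fell, with 1 lower and 1 higher adjusted over the list alone. Mitochondrially encoded transcripts are absent from the tables. None of the 9 blood cell markers was tested, and of the fibroblast markers COL1A2 was the gene called, with 1 of 2 lower in each WT table, over all genes and adjusted over the list alone, and 0 of 1 in ATF4-null cells.

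The genes with a genotype difference by the SE from the statistic at the smallest p were also followed into the tunicamycin table. The 60 genes with a higher WT fold had a median tunicamycin fold of 1.01 (0.82 to 1.19), with 50 called higher and 1 lower, and a median Torin 1 fold of -1.73 in ATF4-null and -0.16 in WT cells. Expression-matched random lists had a median tunicamycin fold of 0.15 (0.01 to 0.30). The WT vehicle group enters both the genotype difference and the tunicamycin fold, so a low value there raises both. Set against the ATF4-null vehicle group instead, across separately scaled tables and without a test, the tunicamycin level of the 60 genes had a median log2 ratio of 0.78 (0.72 to 0.87). For the 542 genes lower with Torin 1 in ATF4-null cells this ratio was 0.04 (-0.02 to 0.11) over 533 genes, beside a median tunicamycin fold of 0.22 (0.16 to 0.30), but these genes were chosen on the ATF4-null vehicle group, which lowers the ratio. The 17 genes with a lower WT fold had a median tunicamycin fold of 0.32 (-0.29 to 0.42) and stood at a centred median of -1.49 (-1.75 to -1.09) in the ATF4-null over the WT vehicle group. Across 10767 genes, which are not independent replicates, folds with Torin 1 in ATF4-null cells and with tunicamycin in WT cells had a Pearson correlation of -0.13 and a Spearman correlation of -0.11. Across 10750 genes the Torin 1 folds of the genotypes correlated at 0.40 and 0.47. A shared shift of composition may account for the first relation, but the overlap of 170 genes would also follow from opposite responses to the treatments. A check of base or codon content was not run.

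Of 77 ribosomal protein genes 40 were higher and 3 lower with tunicamycin, with a list median of 0.47. Expression-matched random lists had a median of 0.33 (0.17 to 0.46), so genes of like expression shared much of this rise. A WT vehicle group that stands apart is argued against. The ribosomal protein genes differed by a median of 0.0579 (-0.02 to 0.11) between the vehicle groups of the genotypes, under the 0.25 of 0.47 set as the bound. A preference for short transcripts in the tunicamycin libraries stays open and may contribute, since 60 other tested genes with a locus of at most 1000 bp had a median of 0.25 (0.06 to 0.54), which is above 0.5 of the ribosomal protein median. The interval also reaches below that bound, and locus length only stood in for transcript length. A response to tunicamycin stays open as well.

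Of the 9 genes lower with both treatments in WT cells, the 8 with FPKM of at least 1 in both vehicle groups stood in ATF4-null vehicle at a centred median of -0.0487 (-1.46 to 0.27) relative to WT vehicle. With COL1A2, which that minimum left out, the median was -0.16 (-1.96 to 0.27). A high value in the shared WT vehicle group cannot be told apart from a response to both treatments, because both intervals are wide and cover both outcomes. COL1A2, at 51.8 FPKM in WT vehicle and at most 2.24 in the other groups, is a gene for which a high WT vehicle value could account for both folds. ELOVL5 is another, with log2 folds of -1.93 with Torin 1 and -1.99 with tunicamycin in WT cells. Its centred log2 ratio of ATF4-null over WT vehicle was -1.96. No test bears on either gene alone. For INSIG1, FCRL5, SLC11A2 and TFRC that ratio was above 0 (0.44, 0.21, 0.06 and 0.27).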
